A study of Arabidopsis thaliana with 16 samples.

How the data were processed

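Total RNA of Arabidopsis thaliana, ecotype Columbia 0, was measured on an expression array in 16 samples, 8 of the wild type (WT) and 8 of the gun5 mutant. The labels describe gun5 as lacking the ChlH subunit of magnesium chelatase. Alleles of gun5 can be point mutations, and whether the subunit was absent was not checked here. The tissue, the age and growth of the plants, the array type, the background correction and the scaling of the values are not given in the sources used here. The authors deposited a single table of relative intensity values on a linear scale for 3439 probes. Values ran from 0 to a highest value just under 100, held by 1 to 4 probes of each sample. It may be a cap, which the sources do not state, so those values may be lower bounds. Each sample averaged just under 1 (0.887 to 0.992), and how that scale was set stays unknown. The table held 0 columns outside these 16 samples. The number of arrays limits the precision of all values.

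Gene names came from the platform annotation, updated through gene identifiers to the RefSeq gene table of assembly TAIR10.1. Of the probes, 692 named 1 gene, 870 named several and 1877 were unnamed here. Only the 692 were named in the text, and 690 of them matched the RefSeq table.

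Values at 0 were treated as missing and the remaining intensities were converted to log2. The sample medians differed by more than 10%, so the log2 values were quantile-normalized, by a rule set before the data were examined. Within a group, a pair of samples counted as 1 replicate if each was the other's nearest sample and the SD of their probe-wise log2 differences was under 0.75 times the median SD of the group's other pairs. On the normalized scale, gun5 samples 1 and 2 (ratio 0.570) and gun5 samples 7 and 8 (ratio 0.644) met this rule and were averaged, which left 8 WT and 6 gun5 replicates. The scale on which to apply the rule was chosen after the data were seen, and the same pairs met it before normalization (ratios 0.607 and 0.678). Gun5 samples 3 and 4, at 0.766, just missed it. Because neighbouring numbers lay close together in general, counts are also given with the numbers 1-2, 3-4, 5-6 and 7-8 averaged, which leaves 4 replicates per group. Nothing in the labels says that samples came from separate plants, so p-values measure only the spread between these samples, which may be technical.

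Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, Benjamini-Hochberg adjustment over 3340 tested probes, threshold 0.05). Another 99 probes had too few values above 0 to be tested. The named genes were those with the 10 largest rises and the 10 largest falls in log2 level among called probes with 1 gene, leaving out the lowest 25% of probes by mean level, and the 2 members with the smallest p of each list with at least 5 measured members. Genes of 17 lists (374 entries) were fixed before the data were examined, and 19 entries had a probe naming that gene alone. The lists with a measured member covered tetrapyrrole synthesis, light harvesting, the photosystems, the Calvin cycle, plastid ribosomal proteins, antioxidants, amino acid synthesis and fatty acid synthesis. Only the plastid ribosomal list reached 5 members. Another 5 lists were added after the number of called genes and the values of the most changed genes had been seen, and 3 of their members were among the values seen. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry.

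The test was checked on simulated data with 200 changed genes among 3262, in 20 simulations. With equal spread in both groups, 4.89% of the calls were false, against a nominal share of 5%. With the spread measured in each group, which was wider in WT, 10.3% were false, so unequal spread by itself makes the adjusted p-values too small. Of genes changed 4-fold, 82.9% were called in that setting, and of genes changed 2-fold, 50.1%. With 4 replicates per group (3253 genes, measured spread), 12.2% of the calls were false, and 77.5% and 34.9% of the 4-fold and 2-fold changes were called. The simulated samples were independent, and far fewer genes changed in them than were called here. Closeness of neighbouring samples was thus not covered, and these shares do not measure the false share of the real calls. Alternatives covered the scaling, the treatment of values at 0, an offset, a filter on dim probes, the variance model, sample weights, the replicate number as a block, the merging of samples and each sample left out in turn.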

Results

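Transcript levels were measured on an expression array in 8 samples of wild-type Arabidopsis (WT) and 8 of the gun5 mutant. GUN5 encodes the ChlH subunit of magnesium chelatase, the enzyme that inserts magnesium into protoporphyrin on the way to chlorophyll, and gun mutants are known from work on signalling from plastids to the nucleus. The groups differed in the distribution of the deposited values themselves. The median relative signal was 0.162 ± 0.0303 in WT and 0.442 ± 0.0355 in gun5 (SD, n = 8 samples each). Probes listed at 0 made up 14.1% ± 3.55 of the table in WT and 5.18% ± 0.491 in gun5 (SD, n = 8 each). The brightest 1% of probes held 48.4% ± 2.95 of the summed signal in WT and 35.1% ± 2.45 in gun5. The log2 interquartile range was 2.35 ± 0.10 in WT and 1.32 ± 0.05 in gun5, with no overlap between the groups.

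**Figure D1:**
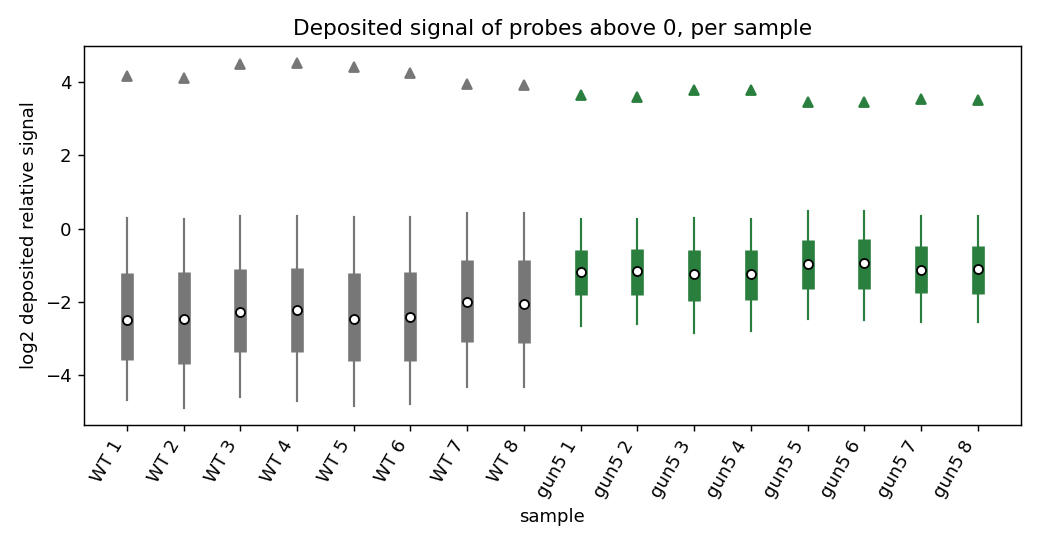
Log2 deposited relative signal (y axis) of the probes above 0 in each sample (x axis), with WT in grey and gun5 in green. Thick bars span the 25th to 75th percentile, thin lines the 10th to 90th, circles mark the median and triangles the 99th percentile. The 8 gun5 samples have higher medians and narrower ranges than the 8 WT samples.

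The comparison of gun5 with WT asks which transcripts differ in a plant with impaired magnesium chelatase. Among the named genes, the clearest single changes were a rise of AT3G56810 and falls of CSLA01, AT2G46630, AT-HF, AT1G78620 and AT3G57630. Only 670 of the 3340 tested probes named 1 gene, so other probes may have changed as clearly. AT3G56810 rose 7.62-fold (log2 change 2.93 ± 0.19 SE, limma adjusted p = 3.29e-07, 8 WT and 6 gun5 replicates), and its deposited signal went from 0.418 ± 0.113 to 3.57 ± 0.888 (SD). CSLA01, a member of the cellulose synthase-like A family of mannan synthases, had a log2 level of -0.24 ± 0.28 in WT and -2.91 ± 0.48 in gun5 (SD), a 6.38-fold fall (limma adjusted p = 1.43e-06). AT-HF, the HISN4 enzyme of histidine synthesis, fell 4.38-fold (log2 change -2.13 ± 0.20 SE, limma adjusted p = 6.13e-06). AT2G46630 fell 4.64-fold, AT1G78620 fell 3.72-fold and AT3G57630 fell 3.29-fold. With neighbouring numbers averaged to 4 replicates per group, these 6 genes had limma adjusted p-values of 0.0020 to 0.0030. The smaller values above count most neighbouring samples as separate replicates. These 6 genes kept their direction and their call under each alternative tried, but not the size of their change. The log2 change of AT3G56810 was 1.90 with median centring and 3.09 without scaling. For the falls the values in the same order were -2.86 and -1.67 for CSLA01, -2.73 and -1.54 for AT2G46630, -2.43 and -1.24 for AT-HF, -2.22 and -1.03 for AT1G78620, and -2.40 and -1.21 for AT3G57630. With a constant subtracted from all gun5 samples, an alternative chosen after seeing the data, they were -3.66, -3.53, -4.09, -3.89 and -2.64 in the same order of genes. AT3G56810 then changed by 2.85.

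The other large rises came from probes that were dim in WT. AT1G22040 rose 4.49-fold (log2 change 2.17 ± 0.34 SE) and AT1G27610 rose 4.06-fold (2.02 ± 0.27 SE), and both were above 0 in all 16 samples. AT5G40070 had a log2 change of 3.44 ± 0.94 (SE), or 2.55 without WT 6, with deposited signals of 0.0764 ± 0.0673 in WT and 0.909 ± 0.136 in gun5 (SD). RAP74, a subunit of the general transcription factor TFIIF, changed by 2.26 ± 0.60 (SE) and AT3G02450 by 3.04 ± 1.09 (SE), each above 0 in 7 of the 8 WT samples. RAP74 lost its call in 6 of 38 alternatives, among them the one with values at 0 set to the lowest value (limma adjusted p = 0.0646). AT3G20680 (log2 change 2.24 ± 0.71 SE) and AT3G26730 (2.04 ± 0.71 SE) were above 0 in 6 WT samples, and AT1G50750 (2.06 ± 0.46 SE) in 5. AT5G48130 (2.64) was above 0 only in WT 4, so the fit had 1 WT value and no WT spread, and its test is not used here. With values at 0 set to the lowest value its log2 change was 6.52. Of the 1327 calls given below, 39 (5 higher and 34 lower) likewise had a single value in a group. The call of AT3G02450 was lost without WT 1, WT 2 or any of gun5 3 to 6 (log2 change 1.99 to 3.42 over all samples left out in turn, limma adjusted p up to 0.0659), and that of AT3G26730 without WT 1 or any of gun5 3 to 6 (1.28 to 2.29, limma adjusted p up to 0.0617). The sizes of these 9 rises are loosely bounded. With an offset equal to the 10th percentile added before the logarithm, the log2 changes were 2.23 for AT5G40070, 1.58 for AT3G02450 and 1.25 to 1.64 for the others, and without scaling they were 3.05 to 4.68, with 3.32 for AT1G22040 and 3.05 for AT1G27610. All 10 rises kept their sign under each scaling, and 7 of the 9 besides AT5G48130 had an adjusted p under 0.05 with 4 replicates per group, the exceptions being AT3G20680 (limma adjusted p = 0.0735) and AT3G26730 (limma adjusted p = 0.0690). With cyclic loess the calls of AT3G02450 (limma adjusted p = 0.107), AT3G20680 (limma adjusted p = 0.0972) and AT3G26730 (limma adjusted p = 0.117) were lost. AT3G02450 also lost its call with the replicate number as a block (log2 change 3.34, limma adjusted p = 0.0738). After the constant was subtracted from gun5, the log2 changes of these 9 rises were 1.88 (AT3G26730) to 3.63 (AT5G40070). AT3G02450 (limma adjusted p = 0.0643), AT3G20680 (limma adjusted p = 0.0643) and AT3G26730 (limma adjusted p = 0.0847) then lost their calls. The others besides AT5G48130 kept theirs. AT3G20680 lost its call in 12 of 38 alternatives, and its log2 change was 1.52 without WT 3.

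The remaining falls were smaller. AT5G14910 changed by -1.67 ± 0.49 (SE), AT4G01810 by -1.58 ± 0.21, AT5G59250 by -1.50 ± 0.23, AT1G51350 by -1.44 ± 0.28 and AT3G50130 by -1.42 ± 0.30 on the log2 scale. Their levels before scaling differed little, with log2 changes of -0.23, -0.15, 0.07, -0.04 and -0.20 in the same order, so these falls are relative to the rise of the typical probe in gun5. All 10 falls had an adjusted p under 0.05 with 4 replicates per group, but without scaling these 5 lost their calls (limma adjusted p = 0.642 to 0.920). With the offset the 5 changed by -1.15 to -1.02, and after the constant was subtracted the 4 that could be tested changed by -5.70 (AT3G50130) to -1.98 (AT5G14910). AT5G14910 and AT3G50130 each lost their calls in 7 of 39 alternatives. AT5G59250, above 0 in 6 WT samples, also lost its call with values at 0 set to the lowest value (log2 change -1.29, limma adjusted p = 0.433).

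**Figure D2:**
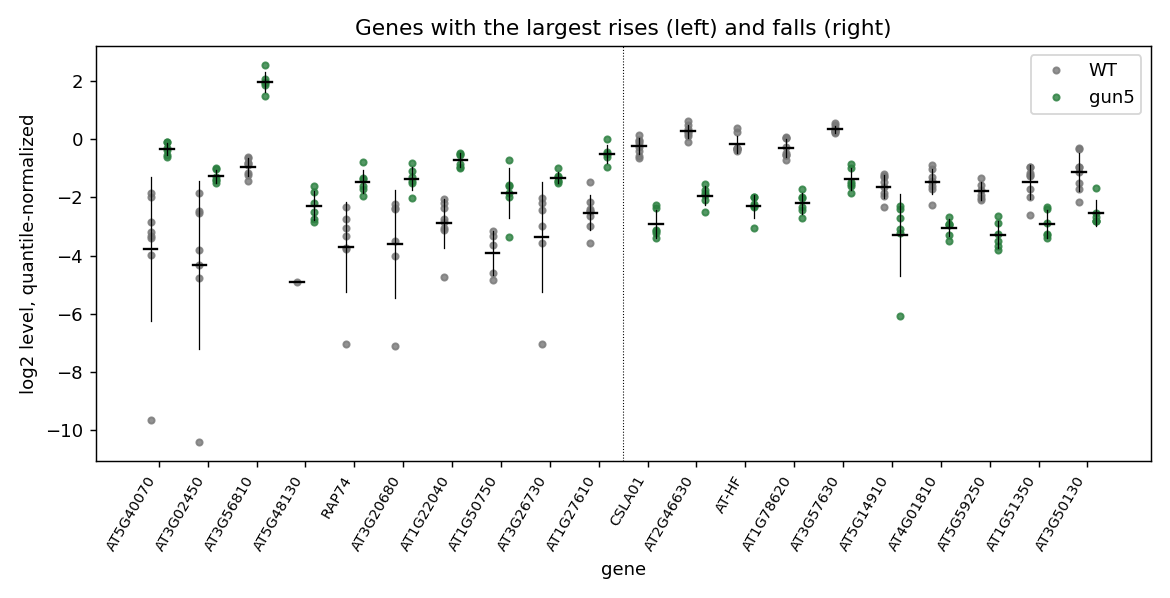
Quantile-normalized log2 level (y axis) of the 10 genes with the largest rises and the 10 with the largest falls (x axis). Points are replicates (8 WT in grey, 6 gun5 in green, fewer where a probe was listed at 0), horizontal bars are means and vertical lines are 1 SD. AT3G56810 and CSLA01 show groups that are apart with little spread, while several rising genes have 1 WT replicate far below the others.

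Genes of tetrapyrrole synthesis were measured by 4 probes, of which 3 rose, 0 fell and 1 did not pass (3 also when adjusted over the list alone). SIRB, the ferrochelatase of sirohaem synthesis, rose by 1.69 ± 0.41 (SE, log2, limma adjusted p = 0.00553). The rise of SIRB was not seen in every gun5 replicate. Its level in the averaged gun5 replicates 7 and 8 (-2.19) lay within the WT range (-4.35 to -1.40). Those of the other gun5 replicates lay at -0.65 to -0.29. The low end of the WT range came from WT 5, and the other WT levels lay at -2.62 to -1.40. HEMA3, a glutamyl-tRNA reductase, rose by 0.93 ± 0.26 (SE, limma adjusted p = 0.0120), but with each sample centred on its median its change was -0.06. Its levels in gun5 5 (-0.30) and gun5 6 (-0.23) lay within the WT range (-1.01 to 0.15), and those of the other gun5 replicates at 0.71 to 1.13. CHLM, the methyltransferase that acts on the product of magnesium chelatase, rose by 0.58 ± 0.21 (SE, limma adjusted p = 0.0433). AT1G74470, geranylgeranyl reductase, had a log2 change of 0.28 ± 0.14 (SE, limma adjusted p = 0.123), which was -1.28 with median centring and -0.09 without scaling. With 4 replicates per group SIRB alone was called. GUN5 itself (CHLH, AT5G13630) had 0 probes naming it alone, so its level was not analysed here and the labels were not checked against the mutated gene.

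Of the 3 photosystem genes, 1 rose, 1 fell and 1 did not pass (the same counts when adjusted over the list alone). PSBW, a small subunit of photosystem II, fell by 0.72 on the log2 scale (SE 0.13, limma adjusted p = 0.000715), and its change was negative under each scaling (-2.53 with median centring, -0.92 with cyclic loess and -1.34 without scaling). PSAN, a subunit of photosystem I, rose by 0.97 ± 0.19 (SE, limma adjusted p = 0.00175) but changed by -0.73 with median centring. PSBY had a log2 change of -0.37 ± 0.19 (SE, limma adjusted p = 0.137). The single light-harvesting gene, LHB1B2, had a log2 change of 0.39 ± 0.18 (SE, limma adjusted p = 0.0935, unadjusted p = 0.0446), which was -1.34 with median centring and -0.15 without scaling. As the only measured member of its list, it has no adjustment over the list alone. The Calvin cycle genes PRK (0.24 ± 0.23 SE) and SBPASE (0.21 ± 0.16 SE) did not pass, nor did AT3G52960, an antioxidant peroxiredoxin (0.19 ± 0.33 SE), or AT3G58610, of branched-chain amino acid synthesis (-0.14 ± 0.25 SE). FATB, a fatty acyl thioesterase and likewise the only measured member of its list, did not pass either. Its log2 change was -0.78 ± 0.36 (SE, limma adjusted p = 0.0976, unadjusted p = 0.0475), and 0.52 without scaling.

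Plastid ribosomal proteins had 6 probes, of which 5 could be tested and 3 rose (3 also when adjusted over the list alone, 0 with 4 replicates per group). AT3G54210 changed by 0.81 ± 0.23 (SE, limma adjusted p = 0.0115), AT4G01310 by 0.76 ± 0.27 (SE, limma adjusted p = 0.0394) and AT3G13120 by 0.56 ± 0.20 (SE, limma adjusted p = 0.0397). AT1G64510 had a log2 change of -0.00494 ± 0.340 (SE) and AT1G29070 of -2.03 ± 1.16 (SE). AT1G29070 was above 0 in only 3 WT samples, against 7 in gun5, and its values at 0 counted as missing. With these zeros included, its mean deposited signal before scaling was 0.0503 in WT and 0.153 in gun5, the opposite direction. Its log2 change, which enters the list mean, is therefore not a reliable fall. The list as a whole did not pass camera (median log2 change 0.56, mean 0.0186, adjusted p = 0.340, and adjusted p = 0.522 with an estimated correlation). The call of AT4G01310 was lost without WT 1, WT 7, WT 8, gun5 3, gun5 4 or gun5 6 (log2 change 0.59 to 0.87 over all samples left out in turn, limma adjusted p up to 0.0907). It was also lost with median centring (log2 change 0.36, limma adjusted p = 0.342) and with cyclic loess (limma adjusted p = 0.135), and in 21 of 39 alternatives in all. With median centring AT3G54210 and AT3G13120 changed by -0.11 and -0.05. After the constant was subtracted from gun5, AT3G54210 changed by 0.519 (limma adjusted p = 0.130) and AT4G01310 by 0.465 (limma adjusted p = 0.2855). Neither was called there.

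**Figure D3:**
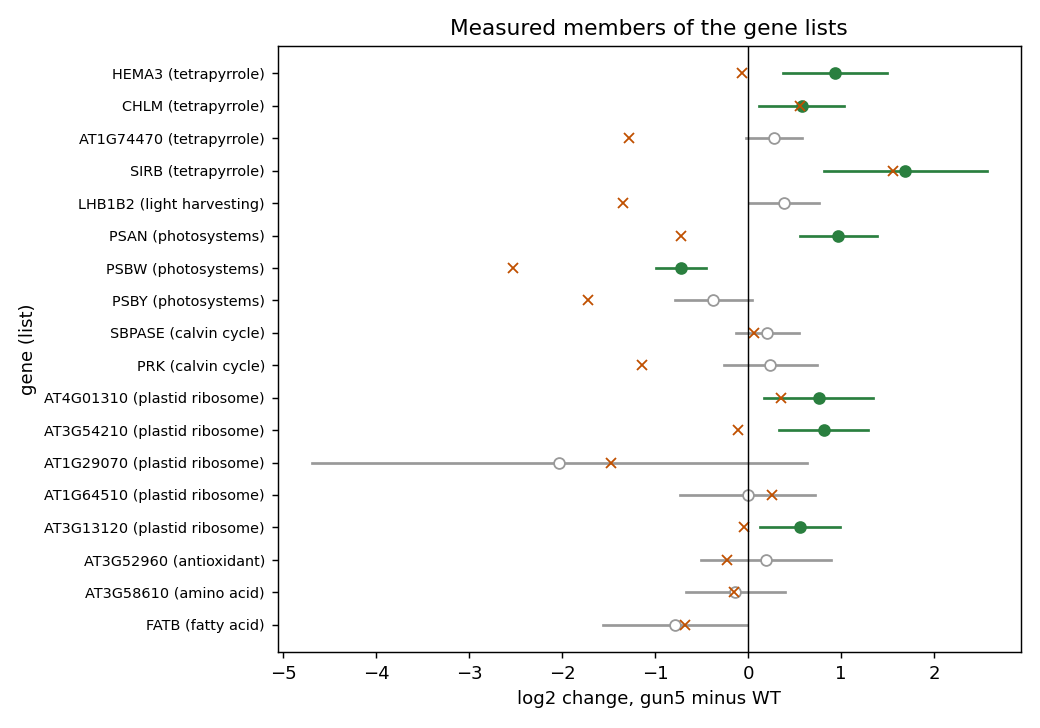
Log2 change in gun5 against WT (x axis) of the 18 tested members of the gene lists (y axis), as points with 95% confidence intervals from limma. Filled green points passed the test and open grey points did not, and orange crosses give the change with each sample centred on its own median. PSBW lies below 0 by both measures, whereas PSAN and HEMA3 lie above 0 as points and below 0 as crosses.

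Across all probes, 1327 of 3340 (39.7%) passed the test, 737 higher and 590 lower in gun5, and 1213 of them changed at least 1.5-fold. Among probes naming 1 gene, 239 of 670 passed, 138 higher and 101 lower. With 4 replicates per group, 880 probes passed (474 higher and 406 lower), and 844 of these were among the 1327, each in the same direction. The share of called probes that were higher depended on the scaling, at 55.5% after quantile normalization, 40.6% with median centring and 92.4% without scaling, where the median log2 change of all probes was 1.18 in place of 0.15. Of the 1327 calls, 381 (269 higher and 112 lower) were also called in the same direction with median centring, with cyclic loess and without scaling.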

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

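The comparison of pairings and the comparison with a scaling factor were chosen after the values they measure had been seen, and the tests with a subtracted constant and with other splits before.

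In 9 of 51 groups of replicates checked, 1 replicate lay far from the others, where chance gives about 1 in 20. That rate belongs to the rule in general and was not measured on values near 0 or on genes chosen for large changes, as many of these were. Most were WT replicates with a very low signal for a gene among the largest rises. WT 6 had a log2 level of -9.66 for AT5G40070, where the other 7 lay between -3.99 and -1.86. WT 5 had -10.41 for AT3G02450, WT 7 had -7.03 for RAP74, WT 3 had -7.11 for AT3G20680, WT 2 had -7.03 for AT3G26730 and -4.75 for AT1G22040. In gun5, replicate 5 had -3.07 for AT-HF, replicate 4 had -6.09 for AT5G14910 (others -3.24 to -2.29) and the averaged replicates 7 and 8 had -1.66 for AT3G50130. Leaving out each such sample on its own left the direction and the call of these genes as they were. AT3G50130 is an exception, since leaving out gun5 7 or 8 keeps the other. With neighbouring numbers averaged and gun5 7 and 8 both left out, its log2 change was -1.68 (limma adjusted p = 0.0278). Without samples 7 and 8 of both groups its log2 change was -1.34 (limma adjusted p = 0.00178). Among the other genes the log2 change fell from 3.44 to 2.55 for AT5G40070 without WT 6, from 3.04 to 1.99 for AT3G02450 without WT 5, from 2.24 to 1.52 for AT3G20680 without WT 3 and from 2.04 to 1.28 for AT3G26730 without WT 2.

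A difference outside the tested probes came from 9 probes listed at 0 in all 8 WT samples and above 0 in all 8 gun5 samples, while 0 probes showed the opposite. By the looser count the order was turned, with 24 probes at 0 in all WT samples and above 0 in any gun5 sample, against 58 at 0 in all gun5 samples and above 0 in any WT sample. The mean relative signal of the 9 probes in gun5 ranged from 0.0432 to 0.490, near or below the gun5 median of 0.442. Only 2 of the 9 name 1 gene, AT3G52550 (0.490 in gun5) and AT4G09970 (0.0848). Fewer probes were at 0 in gun5 in general (5.18% against 14.1% in WT). Whether the 9 go beyond that difference was not tested.

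Values covered a narrower range in gun5 than in WT. Of the 1327 calls, 909 had the same sign under all scalings tried. A scaling factor per sample cannot account for it, because a factor leaves the log2 interquartile range as it is, and that range was 1.32 in gun5 with its highest sample at 1.38, below the lowest WT sample at 2.24. A constant added to every gun5 probe was tested by subtracting 0.288 from all gun5 samples, which brought their median to that of WT. The interquartile range then rose to 2.13 ± 0.07 (SD, n = 8), most of the way, but stayed below the lowest WT sample by more than the bound set beforehand, and 29% of gun5 values fell to 0 against 14.1% in WT. That constant alone therefore did not account for the pattern. Its size was set by matching the medians as deposited, and the range covered only probes still above 0. A constant followed by rescaling and a background that differed between probes were not tested and stay open. A difference in detection at the array and a real difference between the RNA of gun5 and WT were not tested either and stay open too.

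Samples with neighbouring numbers lay close together, clearly so in gun5 and less so in WT. In gun5 the rank correlation was 0.966 to 0.983 within the neighbouring pairs and 0.853 to 0.932 otherwise, and 1 of the 105 ways to pair the 8 samples, the neighbouring one, reached that mean (0.973, highest other 0.953). In WT the ranges overlapped, at 0.762 to 0.891 within neighbouring pairs and 0.738 to 0.851 otherwise. The neighbouring pairing was again the 1 of 105 with the highest mean (0.850, highest other 0.838), although WT 3 and WT 4 were each nearer to WT 6. The pairings were counted after the closeness had been seen. Repeated measurement of one RNA and pairs of plants grown together were not tested.

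The number of called probes exceeded that of all other splits tried. Of 100 splits of the 14 replicates, 1, the real one with 1327 calls, gave as many, and the highest other gave 311. With 4 replicates per group, 1 of the 35 splits, the real one with 880 calls, gave as many, and the highest other gave 4. The real grouping thus stood out among these samples, though with 35 splits the smallest possible share is 1 in 35. Samples of a group may be repeated measurements of one RNA. The splits therefore cannot exclude chance differences between the plants sampled, and say nothing of whether the difference is biological or technical.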

How the results depend on the processing

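The settings that leave out samples 7 and 8 or a neighbouring pair, keep only probes above 0 throughout, subtract a constant or combine averaging with the block, and all values of the 5 added lists, were chosen after seeing the data. Unless stated, the cause was not tested.

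The number of called probes (1327) was 878 with cyclic loess, 2267 without scaling, 753 at an adjusted p under 0.01 and 880 with 4 replicates per group. From those 880 it was 649, 875, 748 and 777 without WT 1-2, 3-4, 5-6 and 7-8, and 468, 552, 602 and 674 without the same gun5 pairs, with fewer samples. Without samples 7 and 8 it was 1174. Leaving out 1 sample gave 1125 to 1361.

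The share of higher calls (55.5%) was 40.6% with median centring, 50.2% with loess, 92.4% without scaling, 63.4% without the dimmest 25% of probes, 37.2% with values at 0 set to the lowest value, 52.2% at an adjusted p under 0.01, 48.0% for probes above 0 throughout and 23.9% after a constant was subtracted from gun5. With 4 replicates it was 48.7%, 50%, 49.5% and 51.9% without gun5 1-2, 3-4, 5-6 and 7-8. Leaving out 1 sample gave 53.6% to 56.1%.

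With the replicate number as a block, 1032 probes were called, and 850 with the block and 4 replicates. Same-numbered WT and gun5 samples deviated together with correlations of 0.0695 to 0.284, not all over 0.1, and 4 of the 8 correlated best with their own number. With neighbours averaged these were 0.118, 0.142, 0.0865 and 0.325, not all over 0.1, and 3 of the 4 matched best with their own pair.

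The plastid ribosomal median (0.56) was -0.0467 with median centring, 0.0583 with values at 0 set to the lowest value and 1.14 without scaling. The list passed with fry (median 0.56, fry adjusted p = 0.0125), which does not compare the list with other genes. Fry ran on the 4 members with complete values, leaving out AT1G29070 (-2.03, from 3 WT samples above 0). Fry's test for change in either direction gave an adjusted p = 0.310 for the plastid ribosomal list, 7.94e-09 for photosynthesis (12 of 15 genes) and 8.02e-08 for organelle RNA (14 of 23 genes). This test makes no comparison with other genes either, and 39.7% of all tested probes passed. In these last 2 lists, 1 rose and 4 fell of 15, and 1 rose and 4 fell of 23. The small p-values thus show nothing particular to these lists, which were written after the most changed genes had been seen. Leaving out 1 sample gave a plastid ribosomal median of 0.45 to 0.61. The added lists passed in 0 settings with camera, and their medians changed sign as follows. Photosynthesis was -0.77 with median centring, -0.11 with values at 0 set to the lowest, -0.53 after the constant and -0.00663 without gun5 5-6 (4 replicates). Organelle RNA was -0.67 and fibrillins -0.18 after the constant. Mitochondrial genes were -0.45 with values at 0 set to the lowest, -0.0300 with the offset, -0.0318 with the block, -0.31 without samples 7 and 8, -0.24 for probes above 0 throughout, -1.52 after the constant and -0.33 without WT 7-8 (4 replicates), with -0.0812 to 0.55 on leaving out 1 sample (-0.0313 without WT 5, -0.0812 without WT 7). Kinesins were -0.0144 with arrayWeights, -0.81 after the constant and -0.13 without WT 3-4 (4 replicates), with -0.0417 (without WT 4) to 0.66. The kinesins had too few complete probes for fry or an estimated correlation.

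Of 848 values of the 22 named genes under alternatives, 749 kept direction and call, 97 lost the call and 2 changed sign (AT3G54210, -0.11 with median centring, and AT5G59250, 0.0704 without scaling). 10 genes kept both throughout. No setting could be run for GUN5. Signal near 0 limits the dim probes in WT.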

Other observations

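The 5 gene lists described here were written after the most changed genes had been seen, and none passed camera. Of 15 tested genes of photosynthetic complexes, their assembly and the Calvin cycle, 1 rose and 4 fell (camera adjusted p = 0.888, 0.938 with an estimated correlation). The falling genes besides PSBW were AT1G74730, known as RIQ2 and involved in the organisation of grana (-1.02 ± 0.22 SE), PIFI of the NDH complex (-0.93 ± 0.29 SE) and AT1G22700, known as PYG7 and needed for photosystem I assembly (-0.75 ± 0.23 SE). With 4 replicates per group 1 rose and 2 fell, and PIFI (limma adjusted p = 0.0599) and AT1G22700 (limma adjusted p = 0.106) lost their calls. Before scaling these 3 had log2 changes of 0.36, 1.09 and 0.93. Without the members seen before, the list had a median of 0.21 and camera adjusted p = 0.888. Its median (0.19) and mean (-0.0623) differed in sign, and the direction given by camera was lower.

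Of 23 pentatricopeptide repeat and mTERF genes, which serve RNA processing and transcription in organelles, 1 rose and 4 fell (camera adjusted p = 0.888, 0.938 with an estimated correlation, median 0.14 and mean 0.15 although camera leaned lower). AT1G61990 rose by 1.34 ± 0.28 (SE), and AT5G55580 (mTERF9, -1.30 ± 0.31 SE), AT3G22150 (-0.87 ± 0.24 SE), AT3G49740 (-0.67 ± 0.19 SE) and AT1G62150 (-0.58 ± 0.16 SE) fell, while before scaling the last 3 had log2 changes of 0.67, 0.14 and 0.20. With 4 replicates per group 1 rose and 0 fell, and the 4 falling genes lost their calls (limma adjusted p = 0.0578 to 0.109). Without the member seen before, the list had a median of 0.17 and camera adjusted p = 0.931. Among 6 genes of mitochondrial respiration 1 rose, ETFQO (1.03 ± 0.31 SE), with a list median of 0.25, a mean of -0.045 and camera adjusted p = 0.888. That mean includes AT4G02580 (log2 change -2.05), which was above 0 in only 3 WT samples and 1 gun5 sample and is not a reliable fall. Among 5 fibrillins, a family of plastid proteins, 1 rose, AT5G09820 (0.80 ± 0.20 SE), with a list median of 0.80 and camera adjusted p = 0.888. Among 5 kinesins 0 passed (smallest unadjusted p = 0.0205), with a list median of 0.40 and camera adjusted p = 0.888. With an estimated correlation, the camera adjusted p was 0.938 for the mitochondrial genes and the fibrillins.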
